A study of Homo sapiens with 16 samples.

How the data were processed

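RNA was measured in 16 libraries from 4 non-small cell lung cancer lines, H460, H1703, HCC827 and H441, with vehicle or the combination of 5 µM MYCi975 and 25 µM TMP195 for 48 hours, and 2 libraries per line and treatment. Per the labels, cells were treated 1 day after plating in RPMI with 10% serum, RNA was isolated with a NucleoSpin kit, and libraries were made with a SMARTer stranded total RNA kit. The single agents were not analysed here. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with STAR to hg38 (GRCh38) and counted per gene with featureCounts, with no versions given. The annotation release is not given in the sources used here.

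The deposited table holds variance-stabilised gene counts on a log2 scale for 28951 genes, made by the authors after division by a size factor per library. The lowest value, 0.480538, is the transformed count of 0, and the highest was 21.1. Undoing the transformation gave whole reads within 0.02 for 100% of values, so reads were recovered per gene and library. The depth was 8493271 to 13604150 reads in the listed genes, which leaves a gene of few reads with a wide counting error: intervals for such genes cover counting error only. A gene with 0 reads in one group was given a bound against a floor of 3 reads over the group, and one with 1 to 3 reads a ratio with a 95% counting interval, scaled by the size factors implied by the values. Such a bound, given as an at least value, leaves out the counting error of the group that had reads. Symbols, gene types and GRCh38 positions came from GENCODE 29, which held 28846 of the gene IDs, and 28782 had a symbol. Normalised reads are recovered reads divided by the size factors.

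Genes were tested when their mean over the 16 libraries lay at least 1 above the lowest value, which kept 23968 genes and removed 4983. One limma fit of the 8 group means (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust settings) gave the change in each line, the mean change of the 2 responsive lines, that of the 2 non-responsive lines, the difference of these, and the difference between the line classes in vehicle. Adjusted p is by Benjamini and Hochberg with a threshold of 0.05 and no minimum change, and a gene called in all 4 lines passed in each with one direction. All standard errors are from this fit. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 42 lists of a contrast, and counts of members past the threshold were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

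Comparisons, lists, alternatives and the rule for naming genes were written before the data were examined. Named genes had a symbol and passed the threshold in the contrast at hand. They were the 8 largest rises and 8 largest falls over the responsive lines with libraries that did not overlap in either line, the 6 and 6 over the non-responsive lines chosen alike, and the 6 and 6 of the difference in which both responsive lines changed more, or less, than both non-responsive ones. Added to these were 6 and 6 called in all 4 lines, 3 and 3 per line, MYC, HDAC4, HDAC5, HDAC7 and HDAC9, and up to 4 members of each described list with the largest changes. With 2 libraries per group, libraries often fail to overlap by chance, so that part of the rule adds little. A few genes that this rule picks are not reported here.

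The 42 lists were drug targets and partners, MYC targets, nucleotide synthesis, complex I, complexes II to V, mitochondrially encoded mRNAs, mitochondrial ribosome, mitochondrial DNA maintenance, TCA cycle, mitochondrial dynamics, integrated stress response, unfolded protein response, heat shock, NRF2 targets, p53 targets, G1/S, G2/M, apoptosis, glycolysis, hypoxia, cholesterol, fatty acid synthesis, fatty acid oxidation, lysosome and autophagy, MEF2 targets, immediate early genes, interferon-stimulated genes, antigen presentation, NF-kB, TGF-beta, epithelial genes, metallothioneins, LXR targets, off-lineage genes, small nuclear RNAs, ribosomal proteins, proteasome, histones, alveolar genes, squamous genes, other cell types and line identity. They were written from general knowledge. Members not tested for low values included MYCN, MRPL53, FGF21, DERL3, HSPA1B, ACADL, EGR2, RSAD2, HLA-DRA, HLA-DRB1 and TNF.

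The pipeline was tested on simulated data with 23501 genes, the 16 libraries' depths, 200 genes with a mean of at least 20 reads changed alike in all 4 lines, 50 each by 1.5, 2, 3 and 4-fold, and a list of 30 genes changed 1.5-fold. It recovered 46 to 58% of genes changed 1.5-fold and 76 to 86% of those changed 2-fold in single lines, and 84 and 96% over the responsive lines, 80 and 98% over the non-responsive lines. At 4-fold it recovered 100% in each line. Among 23271 unchanged genes it called 44 in H460, 45 in H1703, 33 in HCC827 and 47 in H441, which was 20.3, 19.8, 15.2 and 20.4% of the simulated calls and thus above the nominal 5%, and 25 and 24 over the responsive and non-responsive lines (10.5 and 10.3%). The simulation gave genes of few reads the dispersion of drawn genes of many reads. Of the false calls 36, 35, 25 and 40 in the single lines were in genes with a mean under 20 reads. In the real data such genes made up 12.3% of calls in H460, 13.2% in H1703, 9.50% in HCC827 and 13.6% in H441. Limma voom on the simulated reads made 34, 21, 27 and 18 false calls. Camera called the moved list and 0 of 40 unmoved lists (fry called 1 of 40 in the non-responsive contrast). The simulated genes were drawn independently of each other, so this does not show how camera treats lists of correlated genes.

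Alternatives planned were median centring and quantile normalisation of the libraries, no filter, a filter 3 above the lowest value, no trend and no robust setting, fits of only the lines compared, a replicate block shared by all lines or within each line, a minimum change of 1, leaving out each library in turn, camera with an estimated correlation, and fry. Chosen after the data were seen were limma voom on the recovered reads, the same on reads thinned to the smallest library, and a test of protein-coding genes alone. The classes responsive and non-responsive are the series' own, and no library was left out.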

Results

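Total RNA was sequenced from 4 human non-small cell lung cancer lines after 48 hours with vehicle (DMSO) or with 2 small molecules given together, here called the combination. These were 5 µM MYCi975, an inhibitor of the transcription factor MYC, and 25 µM TMP195, an inhibitor of the class IIa histone deacetylases HDAC4, HDAC5, HDAC7 and HDAC9. The series calls H460 and H1703 responsive and HCC827 and H441 non-responsive. Each line and treatment had 2 libraries, which made 8 groups and 16 libraries of 8493271 to 13604150 reads in the listed genes. The mitochondrial ribosomal RNA MT-RNR2 was the most abundant transcript in every library and took 10.4 to 20.96% of those reads. Replicate libraries correlated at 0.976 to 0.985 across genes, and genes are not independent replicates. Changes are combination minus vehicle on the deposited log2 scale, with the standard error of the limma fit and 2 libraries per group, and a positive change means more RNA with the combination. Gene positions are on GRCh38. Nothing in the labels says that the 2 libraries of a group came from separate cultures. Limma p-values thus measure the spread between these libraries, pooled over the 8 groups. Camera p-values compare the members of a list with the other genes.

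The first question was what happened to the mRNAs of the drugs' own targets. The mRNA of MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) rose in H1703 by 1.34 ± 0.11, from 675 ± 1.18 to 1718 ± 2.29 normalised reads (SD, n = 2), and in HCC827 by 0.60 ± 0.11. Its change was -0.06 ± 0.11 in H460 (adjusted p = 0.774) and 0.26 ± 0.11 in H441 (adjusted p = 0.222). HDAC5 rose in all 4 lines, by 1.82 ± 0.12 in H460, 0.68 ± 0.12 in H1703, 0.65 ± 0.12 in HCC827 and 0.75 ± 0.12 in H441 (highest adjusted p = 0.000993). HDAC9 (ENSG00000048052, chromosome 7, 18086949 to 19002416), itself a known target of MEF2 transcription factors, rose by 1.39 ± 0.26 in H1703, 0.89 ± 0.26 in HCC827 and 1.90 ± 0.26 in H441. In H460 it went from 1 to 12 reads, a ratio of 14.8 with a 95% counting interval of 2.19 to 633. HDAC4 fell in H460 (-0.47 ± 0.12) and H1703 (-0.56 ± 0.12), while its change was 0.18 ± 0.12 in HCC827 and -0.10 ± 0.12 in H441. The HDAC4 responses of the line classes differed by -0.56 ± 0.12 (adjusted p = 0.0018). HDAC7 passed the test in no line, with changes from -0.16 in H1703 to 0.24 in H441.

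Without HCC827 Combo 2 the MYC change in HCC827 was 0.41 (adjusted p = 0.0650), and its call was also lost with neither trend nor robust settings (0.0564) and with only the libraries of that line (0.0527). With only the libraries of the line compared the calls of HDAC5 in H441 (adjusted p = 0.125) and of HDAC9 in H460 (0.0846) and H441 (0.0888) were lost. Without H460 Vehicle 1 the HDAC4 change in H460 was -0.43 (adjusted p = 0.0586). The HDAC9 call in HCC827 (adjusted p = 0.0357) was lost in 8 of the 16 fits that left out 1 library, at the most with adjusted p = 0.207 without HCC827 Vehicle 1, and also with median centring (0.0501) and with neither trend nor robust settings (0.130). HDAC7 in H1703 passed the test at -0.41 with each library centred on its median (adjusted p = 0.0235) and at -0.37 without H1703 Vehicle 2 (adjusted p = 0.0447).

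**Figure D1:**
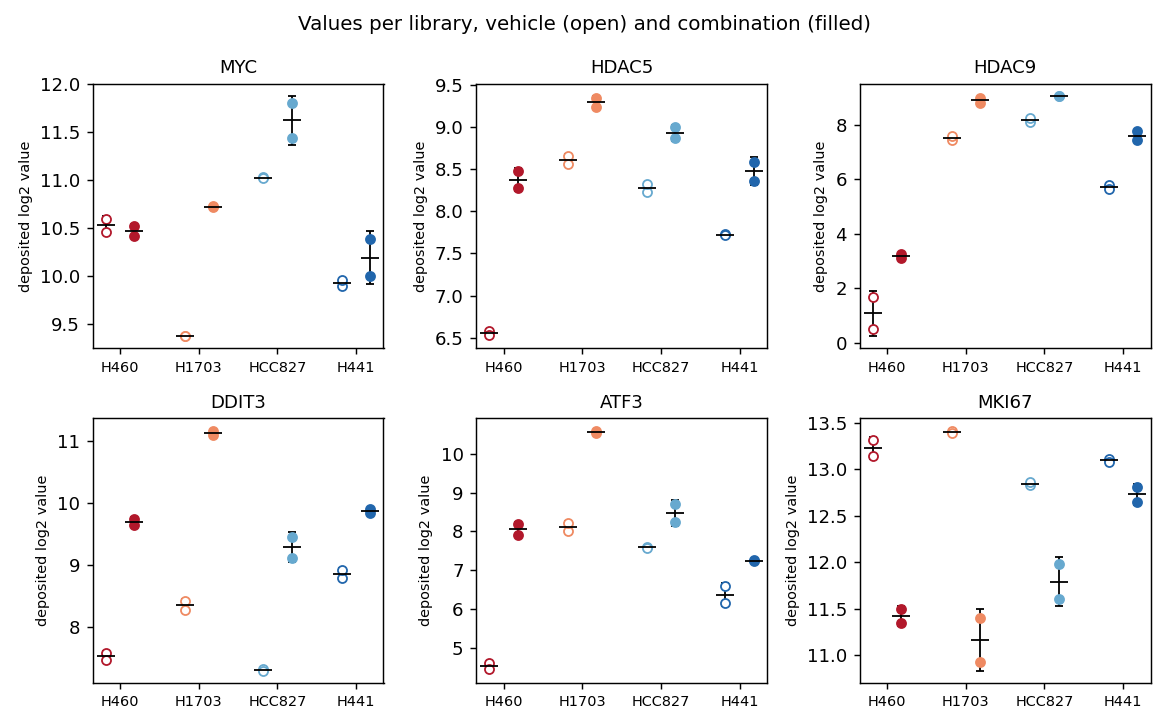
Deposited log2 values (vertical axes) of 6 genes in each library of the 4 lines (horizontal axes), with vehicle libraries as open and combination libraries as filled points and the mean ± SD of 2 libraries as bars. MYC rose by 1.34 in H1703 and differed by -0.06 in H460, while HDAC5, DDIT3 and ATF3 were higher with the combination in all 4 lines.

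In the responsive lines H460 and H1703 the combination raised integrated stress response and immediate early genes and lowered cell cycle, histone and cholesterol synthesis genes. MGLL, which encodes monoacylglycerol lipase, rose by 3.83 ± 0.11 over both lines, from 40.5 ± 1.83 to 509 ± 34.0 normalised reads in H460 (SD, n = 2). GDF15, a secreted stress cytokine, rose by 3.74 ± 0.28, and IGFN1 by 3.83 ± 0.47, from 0 to 40 reads and thus at least 15.0-fold in H1703. The interstitial collagenase gene MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160) went from 2 to 1312 reads in H460, a ratio of 810 (95% counting interval 224 to 6695). It rose by 4.62 ± 0.61 in H1703, together with the neighbouring transcribed pseudogene WTAPP1 (3.92 ± 0.43 over both lines). IL1RL1, the receptor of interleukin 33, went from 1 to 543 reads in H460, a ratio of 670 (120 to 26527), and rose at least 8.60-fold in H1703. ESM1 rose by 6.73 ± 0.58 in H460 and BEX4 by 5.12 ± 0.68 in H1703. ESM1 rested on 1 vehicle read and 16 combination reads in H1703 (ratio 17.95, 2.79 to 753), and BEX4 on 3 and 27 reads in H460 (ratio 11.1, 3.42 to 57.2).

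Among the largest falls over both lines, CDKN2C, a cell cycle inhibitor gene, fell (-3.53 ± 0.16), as did FAM111B (-3.70 ± 0.15) and NRGN (-3.19 ± 0.23). CPLX2 fell (-5.52 ± 0.56) in H460 and had a change of -0.48 ± 0.56 in H1703 (adjusted p = 0.564). The histone genes H2AC12 (-3.34 ± 0.12) and H2AC4 (-3.31 ± 0.14) were also among them, though near-identical histone copies can share reads. Limma called 9232 of 23968 genes, 4945 higher and 4287 lower, with 2848 of them changed by at least 1 on the log2 scale. ESM1 lost its call over both lines with limma voom on the recovered reads, a test chosen after the data were seen (5.08, adjusted p = 0.144).

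Cell cycle genes were lower in both responsive lines. Of 38 G1/S genes 37 fell and 1 rose, with a median of -1.71. RRM2, which encodes a subunit of ribonucleotide reductase, fell (-2.83 ± 0.06), as did the transcription factor gene E2F2 (-2.73 ± 0.17) and the replication gene MCM10 (-2.65 ± 0.07). All 40 G2/M genes fell (median -1.78), among them the mitotic genes KIF20A (-2.56 ± 0.10), SPC25 (-2.51 ± 0.15) and BIRC5 (-2.45 ± 0.08). The 17 replication-dependent histone genes, whose mRNAs carry no poly(A) tail, all fell (median -2.05, -2.07 with members near 0 reads at their bound), as in H2BC11 (-2.92 ± 0.18). Camera adjusted p was 1.04e-37 for G1/S, 3.14e-38 for G2/M and 6.11e-19 for histones, and the counts adjusted over the list alone were unchanged.

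Among nucleotide synthesis genes 17 of 28 fell and 5 rose (median -0.57; 19 and 5 adjusted over the list alone), with TYMS, which encodes thymidylate synthase, at -2.52 ± 0.07. This list held 3 members of the G1/S or G2/M lists, and without them its median was -0.45. Of 65 MYC targets of ribosome biogenesis and the nucleolus 36 fell, 1 rose and 28 were not called (37 lower and 2 higher adjusted over the list alone), with a median of -0.31. The largest of these falls were in MCM4 (-2.45 ± 0.06) and MCM5 (-1.73 ± 0.07), which encode parts of the replicative helicase. Others were in the centriole kinase gene PLK4 (-1.62 ± 0.08) and in HSPE1 (-1.44 ± 0.16), which encodes a mitochondrial chaperonin, and none of these 4 is a nucleolar gene. Camera adjusted p was 1.14e-07 for nucleotide synthesis and 5.05e-11 for MYC targets, and each was lost with adjusted p = 0.0849 with an estimated correlation.

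Chaperone and proteasome genes also fell in the responsive lines. So did part of the nuclear-encoded genes of the respiratory chain, mitochondrial ribosome, mitochondrial DNA maintenance and TCA cycle. Mitochondrial genes as a whole did not, with 7 higher and 7 lower of 20 in mitochondrial dynamics and mitophagy, and 5 and 4 of 21 in fatty acid oxidation. Of 16 heat shock genes 12 fell and none rose (median -1.03, 13 adjusted over the list alone), with HSP90AA1, which encodes a cytosolic HSP90, at -1.62 ± 0.04 and DNAJA1 at -1.48 ± 0.07. Among proteasome genes 27 of 31 fell and none rose (median -0.58, 27 adjusted over the list alone), as in PSMC3 (-1.15 ± 0.07) and PSMD2 (-0.99 ± 0.05). In complexes II to V of the respiratory chain 28 of 39 genes fell and 1 rose (median -0.35; 28 and 2 adjusted over the list alone), as in ATP5MC3 (-1.20 ± 0.08), ATP5F1C (-0.88 ± 0.06) and UQCRFS1 (-0.80 ± 0.10). In complex I 16 of 37 genes fell, with NDUFB10 at -0.85 ± 0.08, and 2 rose (median -0.27, the same counts adjusted over the list alone). One of the rises was NDUFA13 (0.86 ± 0.31, adjusted p = 0.0329), whose call was lost under both other scalings (adjusted p = 0.113 and 0.112). Its call was also lost in 7 of the 16 fits that left out 1 library, at the most with adjusted p = 0.112 without H460 Combo 1.

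Of 75 genes of the mitochondrial ribosome 38 fell and 4 rose (median -0.28; 38 and 5 adjusted over the list alone), with MRPS34 at -0.87 ± 0.08 and MRPS18C, against the trend, at 0.87 ± 0.09. Among genes of mitochondrial DNA maintenance, transcription and import 18 of 34 fell and 7 rose (median -0.35; 20 and 7 adjusted over the list alone). Among them were TFAM, which encodes the packaging factor of mitochondrial DNA, at -1.06 ± 0.06 and the import channel gene TOMM40 at -1.004 ± 0.07. Of 22 TCA cycle genes 14 fell and 1 rose (median -0.35, the same counts adjusted over the list alone), as in IDH3A (-0.76 ± 0.07) and DLAT (-0.73 ± 0.07). Camera adjusted p was 3.48e-12 for heat shock, 6.66e-16 for the proteasome, 7.49e-08 for complexes II to V, 0.000753 for complex I, 4.83e-06 for the mitochondrial ribosome, 0.00211 for mitochondrial DNA maintenance and 0.000142 for the TCA cycle. The calls of the last pair were lost with adjusted p = 0.0849 with an estimated correlation.

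Lipid synthesis and glycolysis genes were lower in the responsive lines as well. Of 24 cholesterol synthesis genes 21 fell and 1 rose (median -0.96, camera adjusted p = 1.40e-14, the same counts adjusted over the list alone), among them ACAT2 (-2.03 ± 0.12) and the sterol feedback gene INSIG1 (-1.99 ± 0.15). In fatty acid synthesis and desaturation 11 of 16 genes fell and 2 rose (median -0.68, the same counts adjusted over the list alone), with the desaturase genes SCD at -1.78 ± 0.13 and FADS2 at -1.44 ± 0.13, the latter called in H460 (-2.53 ± 0.18) and not in H1703 (-0.34 ± 0.18, adjusted p = 0.164). For this list camera adjusted p was 6.37e-06, and adjusted p = 0.115 with an estimated correlation. Among glycolysis genes 12 of 24 fell and 4 rose (median -0.34; 13 and 5 adjusted over the list alone), the falls including PGAM1 (-1.43 ± 0.07) and PKM (-1.23 ± 0.05). Camera gave adjusted p = 0.00127 for glycolysis, and adjusted p = 0.348 with an estimated correlation. ALDOC fell (-1.55 ± 0.23) over both lines and rested on 17 and 1 reads in H1703 (vehicle over combination 15.2, 2.37 to 633). NRF2 targets fell in 15 and rose in 5 of 28 genes (median -0.28, camera adjusted p = 0.00394, the same counts adjusted over the list alone).

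Stress-response and immediate early genes rose in the responsive lines. Of 35 genes of the integrated stress response, the targets of ATF4, 29 rose and 3 fell (median 0.95, 0.94 with members near 0 reads at their bound; 30 and 3 adjusted over the list alone). PPP1R15A, which encodes a regulator of eIF2 alpha phosphatase, rose by 3.29 ± 0.14, the transcription factor gene ATF3 by 2.996 ± 0.12 and CHAC1 by 2.92 ± 0.28. The CHAC1 change was 4.93 ± 0.40 in H460 and 0.91 ± 0.40 in H1703. The rise of the whole stress response list was also smaller in H1703. Its median with members near 0 reads at their bound was 1.42 in H460 and 0.48 in H1703. That of HCC827 was 1.2996 and that of H441 0.59. Median centring gave 1.25, 0.22, 1.26 and 0.58 in the same order. Quantile normalisation gave 1.38, 0.63, 1.35 and 0.55. H1703 was thus lowest except with quantile normalisation, and these differences between lines were not tested. Among immediate early and AP-1 genes 21 of 24 rose and 1 fell (median 1.03, 1.0997 with bounds, the same counts adjusted over the list alone), with the phosphatase gene DUSP5 at 2.53 ± 0.24. Of 22 MEF2 targets and class IIa deacetylase readouts 15 rose and none fell (median 0.89, 1.02 with bounds, the same counts adjusted over the list alone), led by the nuclear receptor gene NR4A1 at 2.77 ± 0.19. EGR1, in both of these lists, had a change of 2.43 ± 0.84 (adjusted p = 0.0487) that was lost under both other scalings (adjusted p = 0.0696 and 0.0614). It was also lost in 13 of the 16 fits that left out 1 library, at the most with adjusted p = 0.145 without H460 Vehicle 2.

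Among cytosolic ribosomal protein genes 50 of 53 rose and none fell (median 0.48, 51 adjusted over the list alone), RPL12 by 1.19 ± 0.07 and RPS27 by 1.07 ± 0.12. The list of drug targets and partners of MYC also held HDAC1, HDAC2, HDAC3, HDAC6, HDAC8, HDAC10 and HDAC11, histone deacetylase genes outside class IIa. Of its 19 members 11 rose and 4 fell (median 0.38, the same counts adjusted over the list alone). They included MXI1, which encodes a MYC antagonist, at 1.21 ± 0.11 and MYCL at 2.11 ± 0.26, the latter with 1 and 7 reads in H460 (ratio 8.64, 1.11 to 390). The nuclear long non-coding RNAs MALAT1 and NEAT1 rose by 2.52 ± 0.10 and 2.14 ± 0.17, and MALAT1 went from 0.160 to 0.192% of all reads in H460 vehicle to 1.21 to 1.35% with the combination. Camera adjusted p was 1.32e-14 for the integrated stress response, 7.27e-10 for immediate early genes, 7.04e-05 for MEF2 targets, 1.75e-19 for ribosomal proteins and 0.039 for drug targets, the last with adjusted p = 0.0849 with an estimated correlation.

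With each library centred on its median, all changes shifted by -0.22 in the responsive lines and -0.21 in the difference of responses, and with quantile normalisation, which moves genes by differing amounts, the median shift was -0.14 and -0.12. The share of called genes that were higher in the responsive lines was 53.6% as deposited and 32.2% with median centring. Relative to the median shift, the list medians were 0.73 for the integrated stress response, 0.81 for immediate early genes, 0.68 for MEF2 targets, 0.26 for ribosomal proteins, -1.93 for G1/S genes, -0.49 for complex I and -0.53 for MYC targets. The drug target list lost its camera call (adjusted p = 0.0519). With an estimated correlation the calls of the G1/S, G2/M, histone, heat shock, proteasome, complex I, complexes II to V, mitochondrial ribosome, cholesterol, NRF2, integrated stress response, immediate early, MEF2 and ribosomal protein lists held in the responsive lines.

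**Figure D2:**
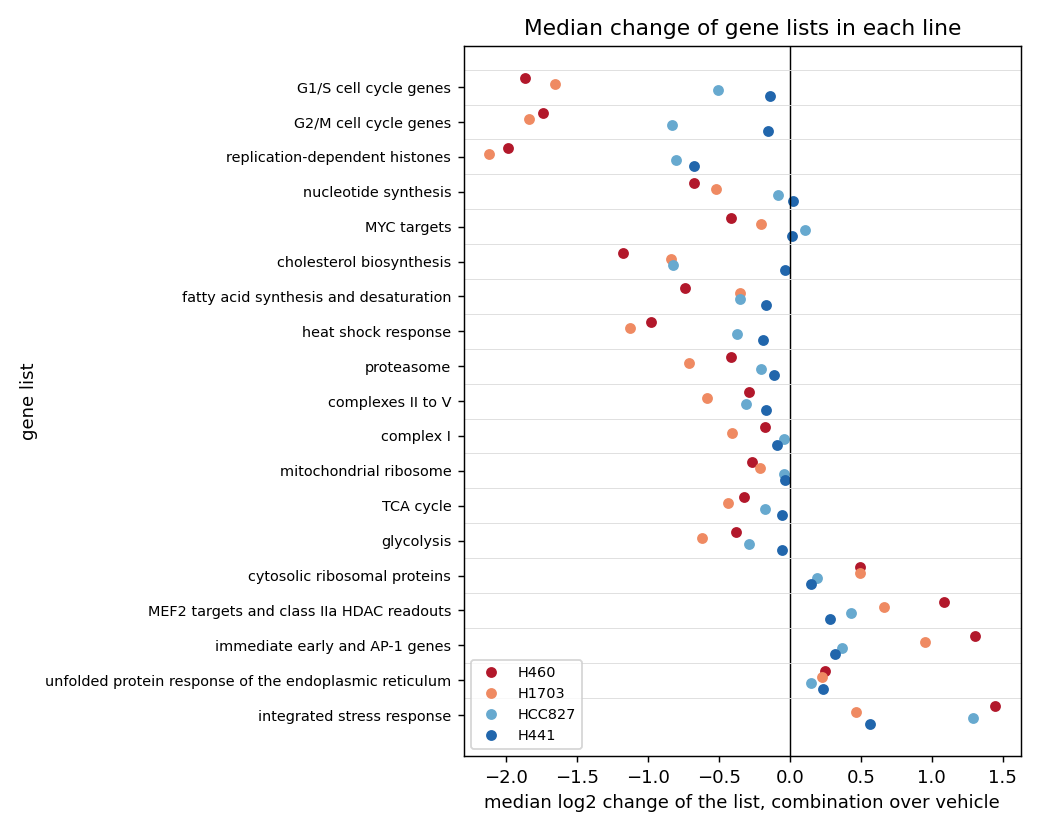
Median log2 change (horizontal axis, combination over vehicle) of 19 gene lists (vertical axis) in each line, 1 point per line from 2 libraries per group. The G1/S and G2/M medians lay between -1.87 and -1.66 in H460 and H1703 and between -0.83 and -0.14 in HCC827 and H441; signs turn under another scaling for nucleotide synthesis and MYC targets in H441 with quantile normalisation, and the unfolded protein response in H1703 with median centring.

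In the non-responsive lines HCC827 and H441 the combination also raised stress-response genes, while cell cycle, sterol and lung lineage genes fell in the mean of both lines. PAPPA2, which encodes a protease of insulin-like growth factor binding proteins, rose by 2.66 ± 0.21, NIBAN1 by 2.12 ± 0.16 and IL23A, which encodes a cytokine subunit, by 2.04 ± 0.26. KRT4, a keratin gene, fell (-3.11 ± 0.20), from 1015 ± 90.4 to 59.0 ± 7.88 normalised reads in HCC827 (SD, n = 2), as did PLEKHS1 (-2.78 ± 0.39) and B3GNT6 (-2.34 ± 0.34). The alkaline phosphatase genes ALPP (-2.64 ± 0.31) and ALPG (-2.66 ± 0.31) fell, and as near-identical copies they can share reads. LRP2 fell (-2.60 ± 0.53), with only 4 and 0 reads in HCC827 (1.42-fold lower against the floor), too few to show a fall in that line. Rises of PYY (1.99 ± 0.44, 0 to 10 reads in H441, at least 2.91-fold), TREX2 (1.97 ± 0.41, 0 to 5 reads in HCC827, 1.56-fold against the floor) and the pseudogene RPLP0P2 (1.97 ± 0.39) rested on few reads or on copies of a parent gene.

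Of 35 integrated stress response genes 29 rose and 1 fell in these lines (median 0.93, camera adjusted p = 5.22e-42; 31 and 1 adjusted over the list alone). ASNS, which encodes asparagine synthetase, rose by 1.87 ± 0.25, GDF15 by 1.65 ± 0.28, CHAC1 by 1.58 ± 0.28 and DDIT3, which encodes the transcription factor CHOP, by 1.49 ± 0.08. CHAC1 rose in HCC827 (2.80 ± 0.40) and had 0.37 ± 0.40 in H441 (adjusted p = 0.727), where GDF15 did not pass the test alone either (1.33 ± 0.39, adjusted p = 0.0624). Among genes of the unfolded protein response of the endoplasmic reticulum 11 of 22 rose and 1 fell (median 0.19; 14 and 2 adjusted over the list alone), with ERN1 at 0.70 ± 0.09, HERPUD1 at 0.60 ± 0.09 and HYOU1 at 0.502 ± 0.06, each called alone in 1 of the 2 lines, ERN1 in H441 and the others in HCC827. For this response camera gave adjusted p = 4.83e-07, and adjusted p = 0.0927 with an estimated correlation. In the responsive lines this list was not called (adjusted p = 0.0758), with 12 higher and 7 lower and a median of 0.22 that was -0.00 under median centring. Immediate early genes rose in 10 of 24 (median 0.33, 11 adjusted over the list alone, camera adjusted p = 3.04e-08). MEF2 targets rose in 7 of 22 with 2 lower (median 0.33; 7 and 3 adjusted over the list alone, camera adjusted p = 0.00129).

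Of 24 cholesterol synthesis genes 18 fell and none rose (median -0.48, 20 adjusted over the list alone, camera adjusted p = 1.30e-17), with INSIG1 at -1.57 ± 0.15, IDI1 at -1.10 ± 0.11 and HMGCS1 at -0.94 ± 0.06. The falls of these 3 genes passed the test in HCC827 and not in H441. HMGCS1 fell in HCC827 (-1.90 ± 0.09), while in H441 the list median was -0.04 and HMGCS1 had 0.02 ± 0.09 (adjusted p = 0.982). Among G2/M genes 33 of 40 fell (median -0.47, 37 adjusted over the list alone), with KIF20A at -1.07 ± 0.10, the proliferation marker MKI67 at -0.71 ± 0.09 and NDC80 at -0.66 ± 0.08. The G2/M fall lay mostly in HCC827, with 36 members called and a median of -0.83 against 3 and -0.15 in H441, and KIF20A had -1.68 ± 0.15 and -0.46 ± 0.15 (adjusted p = 0.0804 in H441, where MKI67 and NDC80 did not pass the test either). For G2/M genes camera gave adjusted p = 4.01e-28, and adjusted p = 0.0927 with an estimated correlation. G1/S genes fell in 23 of 38 (median -0.33, 31 adjusted over the list alone, camera adjusted p = 1.58e-20), 26 in HCC827 alone (median -0.50) and 4 in H441 alone (-0.14), and these differences between the 2 lines were not tested. Histones fell in 15 of 17 (median -0.69, 17 adjusted over the list alone, camera adjusted p = 1.63e-15), and heat shock genes in 8 of 16 with 2 higher (median -0.28, 12 lower adjusted over the list alone, camera adjusted p = 1.09e-06). Complexes II to V fell in 10 of 39 (median -0.18, 14 adjusted over the list alone, camera adjusted p = 1.91e-06).

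Alveolar and club cell lineage genes fell in 6 of 12 and rose in none (median -0.81, -0.87 with members near 0 reads at their bound, 8 adjusted over the list alone, camera adjusted p = 2.05e-05). The surfactant protein gene SFTPB fell (-2.26 ± 0.45), and the falls of AQP4 (-4.44 ± 0.68) and of the near-identical surfactant genes SFTPA1 (-3.40 ± 0.54) and SFTPA2 (-3.24 ± 0.64) were in H441, with at most 5 reads per group in HCC827. Limma called 2946 of 23968 genes over these lines, 1497 higher and 1449 lower, with 369 changed by at least 1 on the log2 scale, and 1932 without HCC827 Combo 2. The camera calls of the integrated stress response, G1/S, cholesterol, histone, heat shock, complexes II to V, immediate early, MEF2 and alveolar lists held with an estimated correlation. AQP4 lost its call over both lines with limma voom on the recovered reads (adjusted p = 0.0506).

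The difference of the responses asks which genes the combination changed more in H460 and H1703 than in HCC827 and H441. MMP1 rose more in the responsive lines by 5.26 ± 0.61, ESM1 by 4.24 ± 0.58, MEGF6 by 3.83 ± 0.21, and IL1RL1 by 3.79 ± 0.54. The same held for ACTN2 (3.68 ± 0.56) and for IL24 (3.59 ± 0.64), each on the strength of 1 line. IL24 had 0 and 97 reads in H460, at least 39.9-fold higher, and 0 and 1 reads in H1703. FAM111B fell more in the responsive lines (-2.91 ± 0.22), as did the histone gene HIST2H2AA3 (-2.87 ± 0.46), MRO (-3.13 ± 0.62), P2RX2 (-2.74 ± 0.77) and the pseudogene PPIAP46 (-3.15 ± 0.71). TREX2 (-2.98 ± 0.58) rested on few reads, with 10 and 2 in H460 and 11 and 3 in H1703, where it did not pass the test, and with 1 and 14 in H441, where it did (combination over vehicle 12.2, 1.86 to 516). MRO was at least 4.16-fold lower in H1703 (14 and 0 reads), and P2RX2 fell from 30 reads to 1 in H460 (vehicle over combination 24.3, 4.04 to 991) and from 12 to 2 in H1703 (5.35, 1.19 to 49.2). PPIAP46 fell from 357 to 3 in H460 (96.4, 32.7 to 470), with no more than 1 read in any other group. Its difference rested on H460 alone. H1703 and HCC827 both had 0 reads of PPIAP46, a tie that does not meet the naming rule for the difference. MRO had 0 and 1 reads in HCC827 and 0 and 0 in H441. P2RX2 had 2 and 4 reads in HCC827 and 1 and 4 in H441. For both genes these lines had too few reads for a fall to be measured. ACTN2 rose by 4.26 ± 0.56 in H1703, had 3 and 7 reads in H460 (adjusted p = 0.333) and was at least 3.20-fold lower in HCC827 (9 and 0 reads).

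G1/S genes fell more in the responsive lines in 37 of 38 (median difference -1.43), G2/M genes in 38 of 40 (-1.29) and histones in 16 of 17 (-1.41), with these counts unchanged when adjusted over the list alone. MYC targets were lower in the difference in 42 of 65 (median -0.40, 45 adjusted over the list alone) and heat shock genes in 11 of 16 (-0.80, 12 adjusted over the list alone). Proteasome genes were lower in 23 of 31 (-0.41, 24 adjusted over the list alone) and nucleotide synthesis genes in 17 of 28 (-0.58, the same number adjusted over the list alone). Immediate early genes were higher in the difference in 11 of 24 (median 0.68, 12 adjusted over the list alone) and MEF2 targets in 9 of 22 (0.51, the same number adjusted over the list alone). Integrated stress response genes were higher in 12 and lower in 7 of 35 (median 0.195, -0.01 under median centring, and 15 and 7 adjusted over the list alone), and camera did not call this list (adjusted p = 0.337).

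Antigen presentation genes were lower in 9 and higher in 1 of 18 in the difference (median -0.56, the same counts adjusted over the list alone), carried mostly by H1703. Their median change was -0.88 in H1703 against 0.12 in H460, 0.29 in HCC827 and 0.27 in H441, and in H460 it was -0.07 with median centring. TAP1, a peptide transporter gene, fell (-2.13 ± 0.17) in H1703 and had 0.08 ± 0.17 in H460 (adjusted p = 0.797). PSMB9, an immunoproteasome gene, fell (-2.50 ± 0.31) in H1703, while CD274, which encodes PD-L1, rose in all 4 lines, by 3.26 ± 0.25 in H460, 1.34 ± 0.25 in H1703 (11 to 33 reads), 0.81 ± 0.25 in HCC827 (adjusted p = 0.0491) and 1.18 ± 0.25 in H441. This list was not called in the responsive lines (4 higher and 9 lower, adjusted p = 0.058). It was called higher in the non-responsive lines (6 of 18, 7 adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.0754 with an estimated correlation). NRF2 targets were lower in 11 and higher in 5 of 28 (median -0.24; 12 and 5 adjusted over the list alone). Among them the cystine transporter gene SLC7A11 fell (-0.58 ± 0.09) in H1703 and rose by 2.23 ± 0.09 in HCC827 and 0.75 ± 0.09 in H441. This gene is also a member of the integrated stress response list. It did not fall in H460, with deposited values of 12.54 and 12.46 in vehicle and 12.69 and 12.56 with the combination.

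Limma called 5594 genes in the difference, 2683 higher and 2911 lower, of which 1704 differed by at least 1 on the log2 scale. Of the genes called in the difference 48.0% were higher as deposited and 23.9% with median centring. In the difference camera gave adjusted p = 8.61e-42 for G1/S, 2.03e-16 for histones, 3.31e-11 for heat shock, 1.02e-11 for the proteasome, 1.28e-11 for nucleotide synthesis, 6.82e-06 for immediate early genes, 0.00022 for antigen presentation, 0.00351 for MEF2 targets and 0.00416 for NRF2 targets. These calls and that of mitochondrial DNA maintenance held with an estimated correlation. Camera adjusted p was 2.03e-16 for MYC targets and 2.25e-36 for G2/M, with adjusted p = 0.0537 and 0.0541 with an estimated correlation. With limma voom on the recovered reads the difference was not called for MMP1 (adjusted p = 0.185), ESM1 (0.557), IL1RL1 (0.105), PPIAP46 (0.282) and CD274 (0.355). With 2 lines per class the test speaks of these 4 lines and not of response classes.

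Genes that moved in all 4 lines showed which part of the response was shared. PAPPA2 rose in every line, from 1.69 in H441 to 4.57 in H460, and so did UNC13A (1.40 to 5.35), the kinesin gene KIF21B (1.49 to 2.96), PPP1R15A (0.96 to 3.77), DUSP5 (1.23 to 3.58) and ASNS (1.29 to 2.44). KRT4 and the histone genes H2AC4, H2AC12, H2BC17 and H1-5 fell in every line, H1-5 from -0.68 in H441 to -3.05 in H1703. KRT4 was at least 5.13-fold lower in H460 (19 and 0 reads) and had only 2 and 0 reads in H1703, too few to support the call there. In all, 121 genes rose and 92 fell in every line, and 984 genes were higher in one line and lower in another. With only the libraries of each line in its fit limma called none in all 4 lines, against 583 at an unadjusted p under 0.05 and 258 with limma voom on all libraries.

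The count of 213 genes was 141 without HCC827 Combo 2, 95 without H441 Vehicle 1, 100 without H441 Vehicle 2, 110 without H441 Combo 1 and 101 without H441 Combo 2. Among the named genes the shared call was lost in 11 of 16 such fits for UNC13A (at the most adjusted p = 0.341, without H441 Vehicle 1), 10 for ASNS (0.226, H441 Combo 1), 8 for DUSP5 (0.156, HCC827 Combo 2), 5 for H2AC12 (0.113, H441 Vehicle 1), and 4 for H2BC17 (0.232, H441 Vehicle 1). It was lost in 3 for PPP1R15A (0.0985, H441 Combo 2), 2 for H2AC4 (0.0677, H441 Vehicle 1) and H1-5 (0.0605, H441 Combo 1), and 1 for KIF21B (0.0531, H441 Combo 2). With limma voom on the recovered reads the shared call was lost for UNC13A (adjusted p = 0.704), PPP1R15A (0.102), DUSP5 (0.205) and KRT4 (0.397), and with quantile normalisation for ASNS (0.0509).

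Each line also had its own largest changes. In H460 the largest falls were in PPIAP46, CPLX2 and NEFH, a neurofilament gene that went from 88 reads to 1 (vehicle over combination 71.3, 12.5 to 2847). In H1703 NGFR, the gene of the p75 neurotrophin receptor, rose by 5.06 ± 0.44, from 41.3 ± 12.2 to 1441 ± 43.5 normalised reads (SD, n = 2), and CDKN2C fell (-4.87 ± 0.23). In HCC827 PAPPA2 (3.63 ± 0.30), NIBAN1 (3.26 ± 0.23) and TMEM178A (0 to 19 reads, at least 5.93-fold) rose. In that line KRT4 (-4.04 ± 0.28) and CAVIN2 (-3.85 ± 0.19) fell together with CAVIN2-AS1, an overlapping antisense transcript (31 to 0 reads, at least 11.03-fold lower). In H441 KRT81 (2.90 ± 0.48), HSD11B1 (2.76 ± 0.51) and the pseudogene TMSB4XP4 (ratio 23.6, 3.88 to 964) rose. In that line AQP4, LRP2 (-3.56 ± 0.75) and the prostaglandin transporter gene SLCO2A1 (23 to 0 reads, at least 8.79-fold lower) fell. Leaving out 1 library ended the LRP2 call in 3 of 16 fits (adjusted p up to 0.120, without H441 Combo 2), and that of TMSB4XP4 in 14 (up to 0.304, without H441 Vehicle 1).

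Limma called 6398 genes in H460, 8500 in H1703, 2378 in HCC827 and 1110 in H441, and 2501, 3812, 518 and 283 of them changed by at least 1 on the log2 scale. With median centring all changes shifted by -0.19 in H460 and -0.24 in H1703, and the share of called genes that were higher went from 52.7 to 32.6% in H460 and from 50.4 to 31.1% in H1703. The HCC827 count was 1214 without Vehicle 1, 1403 without Vehicle 2 and 1013 without Combo 2 of that line, and the H441 count was 520 without Vehicle 1, 499 without Vehicle 2, 575 without Combo 1 and 516 without Combo 2. With only its own 4 libraries, limma called 3626 genes in H460, 8350 in H1703, 1299 in HCC827 and 0 in H441, where 4622 had an unadjusted p under 0.05. Limma voom then called 4670, 10256, 2636 and 357. On simulated data 15.2 to 20.4% of the genes called in a single line had not been changed, most of them genes with a mean under 20 reads. Fewer genes were changed in that simulation than were called in any line here, so this share does not carry over to these counts.

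**Figure D3:**
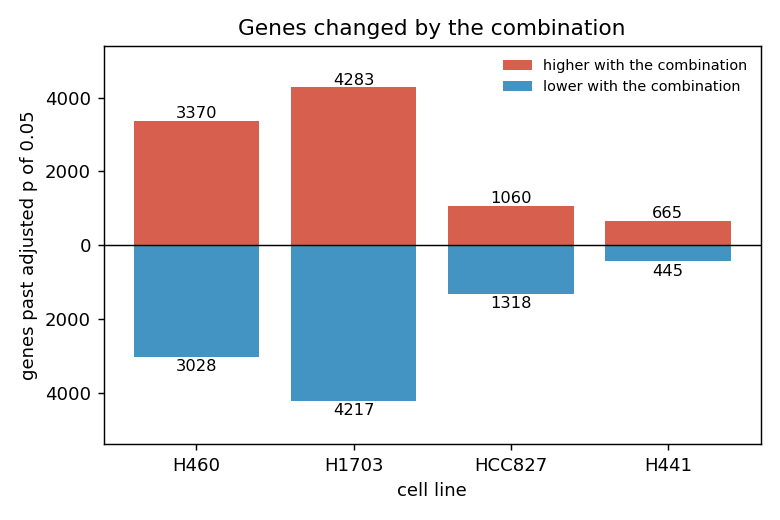
Number of genes past an adjusted p of 0.05 (vertical axis) in each line (horizontal axis), with genes higher with the combination above and genes lower with it below the 0 line, from 2 libraries per group. H460 and H1703 had 6398 and 8500 such genes and HCC827 and H441 had 2378 and 1110.

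Across all tested genes the changes correlated most between H460 and H1703 (r = 0.34) and least between H460 and H441 and between H1703 and H441 (0.13 each). The other values were 0.23 for H1703 and HCC827, 0.21 for H460 and HCC827 and 0.15 for HCC827 and H441. With the strict filter, which drops genes of few reads, all 6 were higher, at 0.46 for H460 and H1703, 0.38 for H1703 and HCC827, 0.35 for H460 and HCC827, 0.29 for HCC827 and H441, 0.23 for H460 and H441 and 0.21 for H1703 and H441. Genes are not independent replicates, and the values describe 6 pairs of lines. Without the error variance the SD of changes was 0.664 of 0.820 in H460 and 0.785 of 0.884 in H1703. It was 0.349 of 0.590 in HCC827 and 0.285 of 0.557 in H441. Error thus lowers the correlations more in pairs with HCC827 or H441, and their ranking does not show which lines responded most alike. H460 and H1703 shared 1552 higher and 1924 lower genes, against 602 and 533 if calls were independent over all tested genes, and 583 were opposite. HCC827 and H441 shared 239 higher and 148 lower genes against 29.4 and 24.5. Pairs across the classes exceeded this expectation too, from H460 and HCC827 (542 and 729 against 149 and 167) to H1703 and H441 (315 and 234 against 119 and 78.3). Genes under 20 reads held only 9.50 to 13.6% of calls in each line, so the expectation is too low and the excess overstated.

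Mitochondrially encoded mRNAs moved apart in the responsive lines. In H460 8 of 13 genes rose and none fell (median 0.61, 9 adjusted over the list alone), with the complex I subunit gene MT-ND4L at 1.22 ± 0.12 and the cytochrome oxidase gene MT-CO1 at 1.11 ± 0.05. In H1703 6 fell and 3 rose (median -0.58; 7 and 3 adjusted over the list alone), with the ATP synthase genes MT-ATP6 at -1.52 ± 0.13 and MT-ATP8 at -1.43 ± 0.19. Those 2 genes had 0.12 ± 0.13 and 0.13 ± 0.19 in H460 and did not pass the test there. MT-ATP6 and MT-ATP8 share one mRNA, as do MT-ND4 and MT-ND4L, so the counts are of genes and not of separate mRNAs. In HCC827 2 of the 13 fell (median -0.28) and 1 in H441 (median -0.35), 2 and 4 adjusted over the list alone. The list had camera adjusted p = 4.52e-05 in H460 and 0.0159 in H1703, and adjusted p = 0.291 and 0.571 with an estimated correlation. The MT-CO1 call in H460 was lost with quantile normalisation (0.31, adjusted p = 0.169), which turned MT-CO1 in H1703 from a called rise of 0.15 (adjusted p = 0.0206) to a called fall (-0.59, adjusted p = 0.0121). The H460 and H1703 medians were 0.41 and -0.83 with median centring and 0.39 and -0.49 with quantile normalisation. In H460 MT-ND2 lost its call under both, MT-ND3 with median centring and MT-ND1 with quantile normalisation. In H1703 median centring added called falls of MT-ND1, MT-CO2 and MT-ND6 and ended the called rises of MT-ND4 and MT-CO1. Quantile normalisation ended the MT-ND2 call there.

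**Figure D4:**
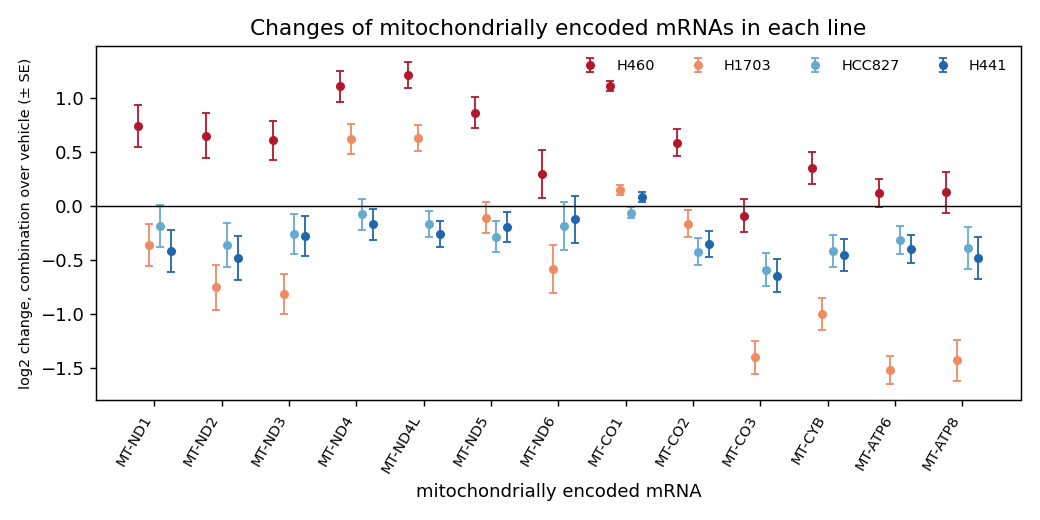
Log2 change of each of the 13 genes of mitochondrially encoded mRNAs (horizontal axis) with the combination (vertical axis), as points for the 4 lines with bars of ± 1 standard error from 2 libraries per group. H460 spans -0.09 to 1.22 and H1703 -1.52 to 0.63; signs turn under another scaling for MT-ATP6 and MT-ATP8 in H460, MT-CO1, MT-CO2 and MT-ND5 in H1703 and MT-ND4 in HCC827.

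The vehicle libraries asked how the responsive and non-responsive lines differed before treatment. All 25 epithelial genes were lower in H460 and H1703 (median -4.71, camera adjusted p = 9.92e-20, the same count adjusted over the list alone). Among them were the keratin gene KRT7 (-10.35 ± 0.12) and the E-cadherin gene CDH1 (-10.27 ± 0.16, a size set by the floor of the scale, with 1 vehicle read in H460 and 20 in H1703). NRF2 targets were higher in 24 and lower in 2 of 28 (median 1.14, camera adjusted p = 2.05e-08, the same counts adjusted over the list alone). AKR1C1 and AKR1C2 were among them, with 10639 and 4800 vehicle reads in H460, 64 and 20 in H1703 and no more than 4 in HCC827 or H441, though near-identical genes can share reads. HDAC4 was higher by 2.06 ± 0.09 in the responsive lines. The pooled values of HDAC9 (-2.65 ± 0.19) and MYC (-0.52 ± 0.08) were lower there, but the lines did not part by class. HDAC9 had 0.497 ± 0.703 normalised reads in H460 and 182 ± 12.96 in H1703 against 291 ± 21.8 in HCC827 and 50.1 ± 3.77 in H441, and MYC 1504 ± 99.2 and 675 ± 1.18 against 2115 ± 17.1 and 990 ± 29.4 (SD, n = 2). Limma called 13502 of 23968 genes, 6895 higher and 6607 lower, of which 6935 differed by at least 1 on the log2 scale. Both list calls held with an estimated correlation, and lines differ in many ways besides the class the series gives them.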

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

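The tests of depth, of spread, of library scaling, of nuclear RNA and of one factor for the mitochondrial transcripts were chosen after the patterns they address were seen, and that of other splits was not. For depth and spread the limits were set before the tested values were seen. Groups held 2 libraries, too few to test any single library against the others of its group.

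The responses of the responsive and non-responsive lines differed in 5594 genes by the limma test of the difference. Among the named genes that passed this test, a positive value means a larger rise or a smaller fall in H460 and H1703. The positive differences were MEGF6 3.83, MGLL 3.37, PPP1R15A 2.13, ATF3 2.11, GDF15 2.10, UNC13A 2.01, NR4A1 1.99, MALAT1 1.95, SFTPB 1.82, NEAT1 1.66, CHAC1 1.34, CD274 1.305, MT-ND4L 1.14, RPS27 1.01, KIF21B 0.99, DDIT3 0.97, ERN1 0.87, RPL12 0.83, MXI1 0.67, MRPS18C 0.65, MT-CO1 0.62, HERPUD1 0.59 and HDAC5 0.55. Those that include groups near 0 reads, whose size depends on the floor of the scale, were MMP1 5.26, ESM1 4.24, IL1RL1 3.79, ACTN2 3.68, IL24 3.59, BEX4 3.46, ALPP 2.95, NGFR 2.93, WTAPP1 2.67, ALPG 2.66, LRP2 2.63, SFTPA1 2.31, PLEKHS1 2.30, CAVIN2 2.29, CAVIN2-AS1 2.28, IGFN1 2.24, B3GNT6 2.09, SLCO2A1 1.99, SFTPA2 1.95, MYCL 1.64, AKR1C1 1.54 and KRT4 1.09. The negative differences were FAM111B -2.91, HIST2H2AA3 -2.87, NRGN -2.70, CDKN2C -2.55, H2AC12 -2.55, H2AC4 -2.32, RRM2 -2.23, H2BC11 -2.22, MCM10 -2.09, SPC25 -2.07, H1-5 -2.04, H2BC17 -1.98, TYMS -1.92, MCM4 -1.89, E2F2 -1.88, BIRC5 -1.85, SLC7A11 -1.72, KIF20A -1.49, FADS2 -1.46, TAP1 -1.40, ACAT2 -1.34, MKI67 -1.31, PSMB9 -1.27, PLK4 -1.26, HSP90AA1 -1.24, MCM5 -1.21, HSPE1 -1.11, NDC80 -1.06, MRPS34 -1.04, TOMM40 -0.98, PSMD2 -0.96, DNAJA1 -0.94, PGAM1 -0.90, PSMC3 -0.90, ATP5MC3 -0.88, TFAM -0.85, PKM -0.80, UQCRFS1 -0.77, NDUFB10 -0.71, SCD -0.67, DLAT -0.61, HDAC4 -0.56, ATP5F1C -0.54, IDH3A -0.42 and HYOU1 -0.29, and near 0 reads PPIAP46 -3.15, MRO -3.13, TREX2 -2.98, CPLX2 -2.85, P2RX2 -2.74, NEFH -2.19, HSD11B1 -1.44, CDH1 -1.03 and ALDOC -0.96. With quantile normalisation the difference of MT-CO1 was -0.14 (adjusted p = 0.601), the opposite sign, since MT-CO1 then had changes of 0.31 in H460 and -0.59 in H1703. With median centring it was 0.41, so the sign turned only with quantile normalisation, which sets values by rank. The difference was not called for SFTPB with either other scaling (adjusted p = 0.0638 with median centring and 0.0817 with quantile normalisation), for KIF21B with median centring (0.0517) or for SCD with quantile normalisation (0.0509). With limma voom the difference of AKR1C1 was not called (adjusted p = 0.0990). A difference between lines that were each at few reads in one class is a difference in what could be measured as well as in response.

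Medians of the difference in the lists that camera called were 0.37 for mitochondrially encoded mRNAs, 0.51 for MEF2 targets, 0.68 for immediate early genes, 0.33 for cytosolic ribosomal proteins, 0.45 for small nuclear and other structural RNAs and 1.15 for alveolar genes. They were -0.40 for MYC targets, -0.58 for nucleotide synthesis, -0.18 for complex I, -0.17 for complexes II to V, -0.18 for mitochondrial ribosome, -0.21 for mitochondrial DNA maintenance, -0.23 for TCA cycle, -0.80 for heat shock genes, -0.24 for NRF2 targets, -1.43 for G1/S genes, -1.29 for G2/M genes, -0.20 for glycolysis, -0.39 for cholesterol synthesis, -0.35 for fatty acid synthesis, -0.56 for antigen presentation, -0.41 for proteasome and -1.41 for histones. The alveolar value cannot be read as a difference of response, since 6 members were left out for lack of reads in H460 and 6 in H1703, and only 4 could be compared (1.83 with bounds in place of absent reads). With an estimated correlation the difference was not called for MYC targets (adjusted p = 0.0537), G2/M (0.0541), the mitochondrial ribosome (0.0537), complex I (0.104), ribosomal proteins (0.104), complexes II to V (0.127), alveolar genes (0.127), cholesterol synthesis (0.157), the TCA cycle (0.176), fatty acid synthesis (0.229), small nuclear RNAs (0.25), glycolysis (0.38) and mitochondrially encoded mRNAs (0.5, and with fry 0.0736).

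The combination changed 6398 genes in H460 and 8500 in H1703 against 2378 in HCC827 and 1110 in H441. The 3 technical explanations weighed were each tested with the smaller responsive value over the larger non-responsive one. With reads thinned to the total of the smallest library, the ratio of counts was 2.40 (6488, 9069, 2702 and 1310 genes), and with quantile normalisation it was 2.44, so neither total depth nor scaling was the whole cause. MT-RNR2 took from 10.4% of reads in H1703 Vehicle 2 to 20.96% in HCC827 Vehicle 2, so the depth left for other genes was not equal. The SD of changes without the error variance was 0.664, 0.785, 0.349 and 0.285, a ratio of 1.90, so larger spread between replicates in HCC827 and H441 was not the whole cause. The error SD was 0.482 in H460, 0.405 in H1703, 0.477 in HCC827 and 0.478 in H441. These values argue against larger spread as a cause for H460, though the spread was lower in H1703. The fit of all libraries also gave every line the same standard error per gene. A larger response of H460 and H1703 is a hypothesis that stays open, and with 2 lines per class it cannot be assigned to response.

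MALAT1 rose by 2.97 in H460 and 2.06 in H1703, and NEAT1 by 2.78 and 1.51. A larger share of nuclear RNA in the combination libraries would raise unspliced transcripts alike, but 414 sense-intronic transcripts had a median change of 0.138 (SD 0.801) in H460 and 0.520 (SD 0.808) in H1703. Under both other scalings the smallest of the 4 changes was 1.22. A smaller part of the rise in H1703 may still be due to nuclear RNA, since 47 of those transcripts rose and 10 fell there against 10 and 10 in H460. A higher level of these RNAs with the combination stays open as a hypothesis.

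Mitochondrially encoded mRNAs had a median change of 0.61 in H460 and -0.58 in H1703. Under both other scalings the smaller size of these medians was 0.387, so scaling was not the whole cause. One factor for all mitochondrial transcripts would move the 13 genes alike, but the SD of their changes over their standard error was 2.60 in H460 and 4.55 in H1703 (0.948 in HCC827 and 1.197 in H441). MT-ATP6 and MT-ATP8 share an mRNA, as do MT-ND4 and MT-ND4L, so the 13 changes are not independent. In H460 MT-ND4L (1.22) and MT-CO3 (-0.09) differed, as did MT-ND4L (0.63) and MT-ATP6 (-1.52) in H1703. A change in the processing or stability of single mitochondrial transcripts may contribute, as a hypothesis that was not tested.

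Other splits of the same libraries were counted for 4 results. For the responsive lines 1 of 18 splits, the real one, gave as many genes (9232, highest other 4579), and for the non-responsive lines 1 of 18 (2946, highest other 481). For the difference of responses 1 of 3 ways to pair the lines gave as many (5594, highest other 3057), and for vehicle 1 of 3 (13502, highest other 11838). In all 4 the splits are too few for a share under 0.05.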

How the results depend on the processing

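Limma voom on the recovered reads, its repeat at equal total reads and the test of protein-coding genes alone were chosen after the data were seen. None of the results counted here reversed. Outside these counts, MT-CO1 in H1703 was called higher as reported (0.15, adjusted p = 0.0206), not called with median centring (-0.09, adjusted p = 0.286) and called lower with quantile normalisation (-0.59, adjusted p = 0.0121). Quantile normalisation sets values by rank. MALAT1 lay below MT-CO1 in H1703 vehicle (15.56 and 15.38 against 16.10 and 15.99). With the combination MALAT1 lay above it (17.70 and 17.37 against 16.19 and 16.21). MT-CO1 thus lost rank to MALAT1, and the called fall is no evidence of less MT-CO1 RNA. Of 174 results on genes picked by the naming rule 170 kept their direction and side of the threshold with median centring and 170 with quantile normalisation, 171 with no filter, 160 with neither trend nor robust settings, 161 with limma voom, and all 174 with a replicate block shared by all lines. All 170 that such a fit can test held with a block within each line, all 140 left by the strict filter held, and so did all 166 among protein-coding genes. With only the lines compared 131 of 153 held, and over all fits without 1 library 2689 of 2784 did and 94 were lost. Residuals of the 28 pairs of groups correlated at -0.0218 to 0.0319 by replicate number over all tested genes. Between vehicle and combination of one line they correlated at 0.0319 in H460, 0.0136 in H1703, 0.0267 in HCC827 and 0.0166 in H441. Counting noise lowers such values, so a batch shared by replicate number was not excluded. Of 68 results on gene lists 66 held with median centring, 68 with quantile normalisation, 65 with fry and 33 with an estimated correlation. The lone library left in a group when the other is taken out is assumed to vary like those of the other groups.

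With only the lines compared, limma called 3626 genes in H460, 8350 in H1703, 1299 in HCC827 and 0 in H441, where 4622 had an unadjusted p under 0.05, and limma voom called 4670, 10256, 2636 and 357. Limma then called 0 in all 4 lines, with 583 at an unadjusted p under 0.05, against 258 with limma voom on all libraries. With neither trend nor robust settings the counts were 1183 in HCC827, 364 in H441, 1674 over the non-responsive lines and 39 in all 4 lines, and with median centring 137 in all 4 lines. A change of at least 1, which by construction leaves fewer genes, gave 2501 in H460, 3812 in H1703, 518 in HCC827, 283 in H441, 2848 over the responsive and 369 over the non-responsive lines, 1704 in the difference, 14 in all 4 lines and 6935 in vehicle. The correlation of responses with the strict filter, which drops genes of few reads, was 0.46 for H460 and H1703, 0.35 for H460 and HCC827, 0.23 for H460 and H441, 0.38 for H1703 and HCC827, 0.21 for H1703 and H441 and 0.29 for HCC827 and H441. Except for the minimum change, whose construction shows it, the cause was not tested.

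Without 1 library the counts ranged from 4886 to 6392 in H460, 6281 to 8785 in H1703, 1013 (without HCC827 Combo 2) to 2740 in HCC827, 499 (without H441 Vehicle 2) to 1432 in H441, 8077 to 9265 over the responsive and 1932 (without HCC827 Combo 2) to 3371 over the non-responsive lines. They ranged from 4880 to 5615 in the difference, 95 (without H441 Vehicle 1) to 277 in all 4 lines and 12456 to 13696 in vehicle. Limma voom called 7021, 9570, 2792 and 1504 genes in H460, H1703, HCC827 and H441, 9687 over the responsive and 3139 over the non-responsive lines and 5315 in the difference. Depth limits genes with a mean under 20 reads, which held 789 of the calls in H460, 1125 in H1703, 226 in HCC827 and 151 in H441 and most false calls on simulated data.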

Other observations

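The genes named in this part were chosen after their values were seen, while the lists were not. The test of silent genes was chosen after the data were seen, with its limits set before its own counts were. Values are over the responsive lines with 2 libraries per group unless another contrast is named.

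Apoptosis regulators were not called as a list, with 11 higher and 3 lower of 29 (median 0.15, camera adjusted p = 0.0653, 11 and 4 adjusted over the list alone). MCL1, which encodes a survival protein of the BCL2 family, rose by 1.52 ± 0.17, and the genes of its antagonist PMAIP1 and of the death receptor TNFRSF10B by 1.16 ± 0.08 and 1.12 ± 0.09. Targets of p53 had 12 higher and 4 lower of 28 (median 0.27, camera adjusted p = 0.058, 14 and 4 adjusted over the list alone). Among them SESN2 rose by 2.58 ± 0.13 and the cell cycle inhibitor gene CDKN1A by 1.48 ± 0.14, and by 1.05 ± 0.14 over the non-responsive lines. SESN2 is also a member of the integrated stress response list. In single lines CDKN1A passed the test in H460 (2.47 ± 0.20) and HCC827 (1.71 ± 0.20) and not in H1703 or H441. Hypoxia genes had 11 higher and 4 lower of 22 (median 0.37, camera adjusted p = 0.00587, 12 and 4 adjusted over the list alone), and adjusted p = 0.115 with an estimated correlation. NDRG1 (1.91 ± 0.12) and DDIT4 (1.60 ± 0.09) rose there and ADM (-1.42 ± 0.24) fell, ADM in H1703 alone (-0.58 ± 0.34 in H460 and -2.26 ± 0.34 in H1703).

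Lysosome and autophagy genes had 15 higher and 7 lower of 35 (median 0.23, camera adjusted p = 0.0288, 16 and 7 adjusted over the list alone), with adjusted p = 0.197 with an estimated correlation and 0.151 with median centring. RRAGD rose by 2.45 ± 0.27 and WIPI1 by 1.64 ± 0.20, and the galactosidase gene GLA fell (-1.29 ± 0.10). Mitochondrial dynamics and mitophagy genes had 7 higher and 7 lower of 20 (median 0.04, camera adjusted p = 0.896, unchanged adjusted over the list alone), with OPTN at 1.15 ± 0.12 and MFN2 at -0.51 ± 0.06. Fatty acid oxidation genes had 5 higher and 4 lower of 21 (median -0.14, camera adjusted p = 0.579, unchanged adjusted over the list alone), with PDK4 at 1.18 ± 0.33 (1.63 ± 0.47 in H460 and 0.74 ± 0.47 in H1703) and HADH at -0.79 ± 0.08. Lipid efflux and LXR targets had 3 higher and 4 lower of 9 (median 0.13, camera adjusted p = 0.351, unchanged adjusted over the list alone), and ABCA1, a cholesterol exporter gene, fell in H460 (-1.23 ± 0.28) and HCC827 (-1.81 ± 0.28), rose by 2.71 ± 0.28 in H1703 and had -0.06 ± 0.28 in H441.

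Interferon-stimulated genes had 4 higher and 5 lower of 29 (median -0.12, camera adjusted p = 0.193, unchanged adjusted over the list alone), and OAS3 fell (-1.78 ± 0.08). NF-kB and inflammatory genes had 10 higher and 2 lower of 23 (median 0.48, camera adjusted p = 0.152, unchanged adjusted over the list alone), where CXCL8 rose by 2.98 ± 0.37 in H460 and had no reads in H1703, and NFKBIA fell (-0.87 ± 0.07). TGF-beta and mesenchymal genes had 10 higher and 3 lower of 25 (median 0.29, camera adjusted p = 0.0584, unchanged adjusted over the list alone), where COL1A1 fell in H460 (-2.15 ± 0.45). Metallothioneins had 2 higher and 0 lower of 4 (median 0.38, camera adjusted p = 0.202, unchanged adjusted over the list alone), with MT2A at 0.18 ± 0.20 in H460 and 2.07 ± 0.20 in H1703. Epithelial genes had 6 higher and 4 lower of 25 (median 0.12, camera adjusted p = 0.351, unchanged adjusted over the list alone), with OCLN at 3.05 ± 0.26 in H460 and 0.29 ± 0.26 in H1703, and squamous lineage genes had 0 higher and 1 lower of 5 (median -0.13, camera adjusted p = 0.601, unchanged adjusted over the list alone), with SOX2 at -2.40 ± 0.39. Alveolar genes had 2 higher and 2 lower of 12 (median -0.15, camera adjusted p = 0.811, unchanged adjusted over the list alone).

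Lists that served as checks of the samples were not called over the responsive lines. Genes of other cell types had 2 higher and 1 lower of 8 (median 0.15, camera adjusted p = 0.973, unchanged adjusted over the list alone). Line identity genes had 1 higher and 4 lower of 9 (median -0.44, camera adjusted p = 0.058, unchanged adjusted over the list alone), off-lineage genes 4 higher and 1 lower of 18 (median -0.18, camera adjusted p = 0.896, unchanged adjusted over the list alone), and small nuclear and other structural RNAs 4 higher and 0 lower of 9 (median 0.18, camera adjusted p = 0.0908, unchanged adjusted over the list alone). In vehicle, off-lineage genes were higher in the responsive lines, with 13 higher and 2 lower of 18 (median 2.88, camera adjusted p = 0.000982, unchanged adjusted over the list alone) and adjusted p = 0.0898 with an estimated correlation. Antisense genes took 1.67 to 1.89% of reads in every library. With median centring the medians over the responsive lines turned to -0.07 for apoptosis regulators, -0.18 for mitochondrial dynamics, -0.10 for epithelial genes, -0.09 for LXR targets, -0.03 for small nuclear RNAs and -0.07 for other cell types.

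Over the non-responsive lines hypoxia genes had 7 higher and 2 lower of 22 (median 0.21, camera adjusted p = 0.00703, 10 and 3 adjusted over the list alone), NF-kB genes 3 higher and 0 lower of 23 (median 0.23, camera adjusted p = 0.0186, unchanged adjusted over the list alone), LXR targets 0 higher and 4 lower of 9 (median -0.55, camera adjusted p = 0.000268, unchanged adjusted over the list alone) and lysosome genes 9 higher and 3 lower of 35 (median 0.12, camera adjusted p = 0.00421, 11 and 3 adjusted over the list alone). With an estimated correlation these gave adjusted p = 0.153, 0.26, 0.0754 and 0.147. Camera also called the proteasome (median -0.17, adjusted p = 4.59e-07), ribosomal proteins (0.14, 2.74e-11), the TCA cycle (-0.11, 0.0211), glycolysis (-0.18, 0.0102), fatty acid synthesis (-0.16, 0.000196) and mitochondrially encoded mRNAs (-0.30, 7.81e-06). With an estimated correlation these gave adjusted p = 0.0754, 0.13, 0.288, 0.471, 0.2 and 0.289. Of the lists that camera called in vehicle none but epithelial genes and NRF2 targets was called with an estimated correlation, for example hypoxia genes (median -0.97, 2.31e-05, then 0.0821) and alveolar genes (-3.004, 0.000384, then 0.0821).

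The hypothesis that the combination switches on more silent genes than it silences in H460 and H1703 was tested on recovered reads thinned to equal totals. The depth left for other genes was not equal, since MT-RNR2 took 11.6 and 10.4% of reads in H1703 vehicle and 15.3 and 13.6% with the combination. In H460 11 genes with no read in either vehicle library gained at least 10 reads and 1 was lost in the same way, and in H1703 12 and 1, so the smaller ratio was 11. The numbers gained and lost were 0 and 2 in HCC827 and 0 and 1 in H441. In H460 they included IL24, CCND2, PTGER3 and IL1RL1, which had 1 vehicle read at full depth, and in H1703 IGFN1, LURAP1L and MYCT1. Some of these genes may be switched on by the combination, but few genes are counted and low expression below the detection limit of these libraries was not excluded.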
